A study of Homo sapiens with 6 samples.

How the data were processed

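Polysome-bound RNA, the RNA recovered with messenger RNAs that carry several ribosomes, was measured by RNA sequencing in LNCaP cells, an established human prostate carcinoma line that responds to androgen. Per the labels, all 6 libraries came from cells treated with enzalutamide, an antiandrogen drug, at 10 µM for 72 h. The libraries form 2 groups of 3 by guide RNA, a control guide (sgControl) and a guide against PRKCI (sgPRKCI), which encodes the atypical protein kinase C iota. RNA was taken up in Trizol and cleaned on a Quick-RNA kit, and libraries were made and sequenced by a service company, per the labels' protocols. Total RNA of the same cells was not analysed here, so no translational efficiency is given and a difference in polysome-bound RNA can come from RNA level or from ribosome loading. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

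The deposited signal values are reads per gene divided by 1 size factor per library, as the values themselves show: within each library every value is a whole multiple of the value of 1 read. After division by that step, 100.0% of the values were whole within a tolerance of 0.001. The submitters' processing notes name STAR, DESeq2, GRCh38 and GRCm39, with no version or role. The counting tool, the annotation, the strand setting and any filter are not given in the sources used here. The table held 19848 genes by symbol, and the gene with the fewest reads had 9 reads over the 6 libraries. Recovered reads per library ranged from 13575323 to 18464360. Counting intervals (95%, exact Clopper-Pearson) and floors of 3 reads cover counting error only, since reads without molecular identifiers are not independent molecules.

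Genes with a mean normalized read count of at least 10 over the 6 libraries were tested, 15418 in all. The test was limma (version 3.58.1, R 4.3.3) with a mean-dependent prior on log2(normalized read count + 1), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are sgPRKCI over sgControl on that scale, which understates the change of low genes, and errors are standard errors of the fit. Fold ratios printed without a log are ratios of reads per size factor summed over each group. Gene lists fixed beforehand, 25 in number, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, with Benjamini-Hochberg adjustment over the 24 lists that qualified. Camera with an estimated correlation and fry were run beside it. Listed members under an older symbol were matched to the symbol in the table, and mitochondrially encoded mRNAs are given under the table's names, such as COX2 for the cytochrome c oxidase subunit. Positions come from a RefSeq annotation of GRCh38.p14 matched by symbol, which held 19346 of the 19848 symbols.

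The groups share replicate numbers in the labels. Deviations from the group means correlated across the 15418 genes by 0.57 for the libraries numbered 1, 0.35 for those numbered 2 and 0.46 for those numbered 3. All 3 correlations exceeded the minimum of 0.1 set for pairing, so the numbers were taken to pair the libraries. Across numbers, sgControl replicate 2 with sgPRKCI replicate 3 (0.22) and sgControl replicate 3 with sgPRKCI replicate 2 (0.23) exceeded it too, so the libraries numbered 2 and 3 also deviate together against those numbered 1, and each library correlated best with its own number. Fits with the replicate number as a block are given where they change a call. No pair of replicate libraries agreed within sampling noise: chi-square per gene ranged from 13.3 to 72.7.

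The named genes followed a rule set before the data were examined, as were the tests and the alternatives, except those said to be chosen later. PRKCI, PRKCZ, EZH2 and KLK3 were always named, and some items that the rule takes are not reported here. So were the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 50 and every sgPRKCI library on one side of every sgControl library. Up to 4 members of each list with the smallest adjusted p could be named. Y-linked genes were counted and not named, and pseudogenes and genes with only a clone identifier were counted only. Any other gene named was chosen after its values were seen, and is said to be so.

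The alternatives were other pseudocounts, filters and scalings, robust variances, library weights, the replicate block, each library left out in turn, and edgeR (4.0.16, quasi-likelihood) and DESeq2 (1.42.0, Wald) on the recovered reads. The fits were tested on simulated counts for the 15418 genes with 200 changed genes. The changed genes were drawn only from those with a mean of at least 50, so recovery of lower genes was not measured. Without pair effects in the simulation, limma recovered 93% of the genes changed by 2 on the log2 scale and 25% of those changed by 1. With pair effects, the recovery of genes changed by 1 was 6% without the block and 96% with it, but 24 of the 220 blocked calls were false, against 0 of 84 without the block. Without pair effects the block lowered that recovery to 11%. The simulated pair effects were observed means of the libraries sharing a number, which hold noise too, so the gain from the block may be overstated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.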

Results

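Polysome-bound RNA was compared between enzalutamide-treated LNCaP cells that carried a guide against PRKCI and cells that carried a control guide, with 3 libraries in each group. The comparison asks which mRNAs differ in the polysome fraction of drug-treated prostate cancer cells when the atypical protein kinase C iota is targeted. The sgControl libraries held 15650884, 14419375 and 13575323 reads for replicates 1, 2 and 3, and the sgPRKCI libraries held 14515347, 18464360 and 17064940. Levels are normalized read counts, given as mean ± SD with n = 3 per group, and adjusted p-values are from limma unless another tool is named.

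The targeted gene itself did not differ detectably between the groups. PRKCI (chromosome 3, 170222424 to 170305977) measured 423.1, 453.3 and 566.1 in sgControl replicates 1, 2 and 3, and 385.2, 522.3 and 603.0 in sgPRKCI replicates 1, 2 and 3. Its log2 fold change was 0.05 (SE 0.21), with an adjusted p of 0.999. Reads summed over a whole gene do not show small insertions or deletions at a guide's site, so this level does not check the labels. PRKCZ, which encodes the other atypical protein kinase C (chromosome 1, 2048504 to 2185395), measured 1090 ± 148 in sgControl and 1010 ± 252 in sgPRKCI. EZH2, the catalytic subunit of the histone H3 lysine 27 methyltransferase complex (chromosome 7, 148807383 to 148884291), measured 513 ± 24.7 and 482 ± 25.3, a log2 fold change of -0.09 (SE 0.15). KLK3, the androgen-induced gene of prostate-specific antigen (chromosome 19, 50854915 to 50860764), measured 14100 ± 4280 in sgControl and 7810 ± 2870 in sgPRKCI. The log2 fold change of KLK3 was -0.87 (SE 0.31), which missed the threshold at an adjusted p of 0.333 and passed it with the replicate block at 0.00342.

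Among 15418 genes tested, 162 differed between the groups, 67 higher and 95 lower in sgPRKCI. Of the 67 higher genes, 13 were Y-linked. All 162 genes had every sgPRKCI library on one side of every sgControl library, as did 2246 of the tested genes (14.57%, where chance gives 10%). With the replicate block 1545 genes differed, 913 higher and 632 lower, and these included all 162. The count changed with the libraries used: it was 937 without sgPRKCI replicate 1, where all 162 were called again. Without sgControl replicate 1, 2 or 3 it was 105, 74 and 81. Without sgPRKCI replicate 2 or 3 it was 95 and 118.

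Outside the Y-linked genes, the largest rise was in CBLN2, which encodes a secreted synaptic organizer of the cerebellin family (chromosome 18, 72536681 to 72638521). CBLN2 rose from 18.9 ± 2.65 to 1260 ± 315, a 65.5-fold difference and a log2 fold change of 5.96 (SE 0.24, adjusted p = 3.99e-05). RIMS1, a scaffold of the presynaptic active zone, rose 14-fold from 9.39 ± 5.32 to 135 ± 27.4. PALM, which encodes the membrane-associated protein paralemmin, rose 10.4-fold to 265 ± 63.5. AGR2, a protein disulfide isomerase of secretory epithelium (chromosome 7, 16791811 to 16804999), rose from 35.3 ± 10.9 to 311 ± 18.5. The homeobox gene IRX2 on chromosome 5 rose from 21.7 ± 1.74 to 123 ± 18.6, and its divergent non-coding transcript IRX2-DT rose from 64.2 ± 2.93 to 401 ± 31.4. HYCC1, whose product belongs to the complex that brings phosphatidylinositol 4-kinase to the plasma membrane, rose from 177 ± 32.4 to 1030 ± 55. PARVA, which links integrins to actin, rose from 90.5 ± 34.9 to 453 ± 20.2, and the non-coding RNA COLCA1 rose from 68.3 ± 12.6 to 375 ± 121. The transcription factor gene SOX11, the kinesin gene KIF26A and the transglutaminase gene TGM2 had log2 fold changes of 2.53, 2.94 and 2.44. SOX11, KIF26A and TGM2 each lost the threshold under some alternatives, among them the fit without sgPRKCI replicate 2, where RIMS1 lost it as well.

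The largest fall on the log2(normalized read count + 1) scale, -7.81, was in MAGEA8, a cancer/testis antigen gene on chromosome X (149881183 to 149885825), which fell from 468 ± 257 to 1.96 ± 3.4, a 311-fold difference (adjusted p = 0.00247). MAGEA8 measured 5.9, 0 and 0 in sgPRKCI replicates 1, 2 and 3, so that ratio rests on the reads of sgPRKCI replicate 1. The cancer/testis genes PAGE5, PAGE2B and CTAG2, also on chromosome X, fell 204-fold, 75.3-fold and 51.7-fold. GAGE1 fell from 602 reads over the sgControl libraries to 2 reads over the sgPRKCI libraries, a ratio of normalized reads of 360 with a 95% counting interval of 99.1 to 2980. GTSF1, which acts with piRNAs in transposon silencing (chromosome 12, 54455957 to 54473602), measured 102 ± 20.5 in sgControl and had no read in any sgPRKCI library. GTSF1 was at least 112-fold lower against a floor of 3 reads over the group. SYCE1, a component of the meiotic synaptonemal complex, fell from 128 ± 10.3 to 2.09 ± 1.94. MT1G, a metal-binding metallothionein (chromosome 16, 56666730 to 56668065), fell from 472 ± 133 to 2.14 ± 0.353, a 221-fold difference (adjusted p = 3.99e-05). RSPO4, a secreted enhancer of Wnt signalling, fell 36.5-fold, and JPH3, which ties the endoplasmic reticulum to the plasma membrane, fell 25.4-fold. The non-coding RNAs DSCR8 and DPP10-AS1 fell 72.2-fold and 29.8-fold, and DSCR8 lost the threshold without sgControl replicate 2, sgControl replicate 3 or sgPRKCI replicate 2. DSCR8 measured 13, 2.3 and 0 in sgPRKCI replicates 1, 2 and 3, so its ratio rests mostly on sgPRKCI replicate 1. GAGE1, PAGE2B, CTAG2 and MT1G have near-identical relatives and DPP10-AS1, COLCA1, GTSF1, PAGE2B, SYCE1, RIMS1 and CBLN2 overlap other annotated genes, so their own values are uncertain where the counting could split reads.

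**Figure D1:**
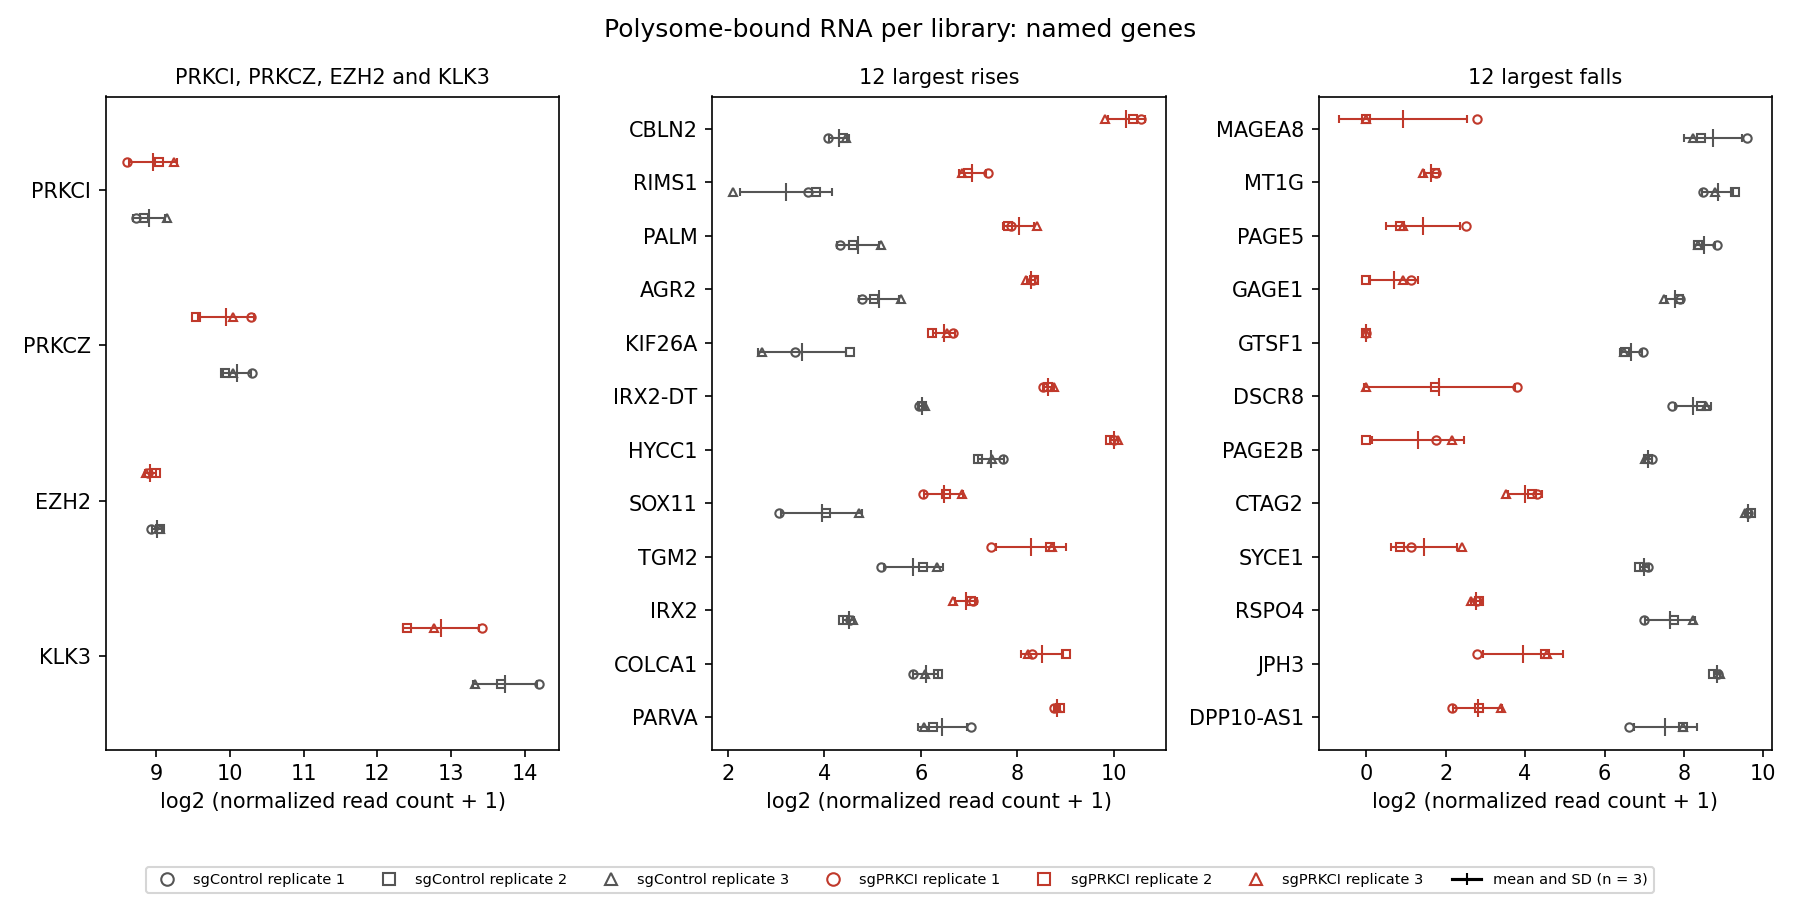
Normalized read counts of named genes in each of the 6 libraries, as log2(normalized read count + 1) on the horizontal axis of each panel. Symbols are libraries by replicate number, grey for sgControl and red for sgPRKCI, and bars give the mean and SD (n = 3); CBLN2 and the other 11 rises and the 12 falls show no overlap between groups, while PRKCI, PRKCZ, EZH2 and KLK3 overlap.

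The TGF-beta and fibroblast lists were shifted up in the sgPRKCI group by camera at the preset correlation and not with an estimated one (adjusted p = 0.981 for each), with larger differences in pairs 2 and 3 than in pair 1. Of 42 tested TGF-beta response and mesenchymal genes, 1 rose, none fell and 41 did not pass, with a median log2 fold change of 1.75. The gene that rose was TWIST1, a transcription factor of mesenchymal identity, from 11.3 ± 4.67 to 66.4 ± 18.1 (log2 fold change 2.49, SE 0.38, adjusted p = 0.0229), with pair differences of 2.19, 3.01 and 2.26. ZEB1 measured 10.2 ± 2.92 and 78.1 ± 51.1, and the TGF-beta receptor gene TGFBR2 measured 37.3 ± 6.56 and 174 ± 104. Adjusted over the list alone 21 of the 42 rose, and with the replicate block 29 did so over all genes. Of 10 fibroblast genes tested none passed over all genes, 10 passed adjusted over the list alone and 9 passed with the block. COL1A2, a chain of type I collagen, measured 693.5, 797.7 and 487.8 in sgControl replicates 1, 2 and 3, and 815.2, 12276.1 and 12825.5 in sgPRKCI replicates 1, 2 and 3. The fibroblast list had a median of 2.96, and its pair medians were 0.33, 3.73 and 4.67 for pairs 1, 2 and 3. The TGF-beta list had pair medians of 0.24, 2.33 and 2.36. By camera both lists were higher, at adjusted p-values of 5.18e-16 for TGF-beta and 1.47e-08 for fibroblast genes. With sgPRKCI replicates 2 and 3 left out the fibroblast call was lost, at a median of 0.31 (adjusted p = 0.229), while the TGF-beta list still passed, at a median of 0.22 (adjusted p = 0.0361).

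Neuroendocrine and basal epithelial markers were also higher as lists, by more in pairs 2 and 3, where the fibroblast genes stood high, than in pair 1. Camera gave adjusted p-values of 7.24e-05 for the neuroendocrine and 0.00964 for the basal list, and 0.981 for each with an estimated correlation. No neuroendocrine marker of 17 tested passed over all genes, 5 rose adjusted over the list alone, and the median was 0.84 with pair medians of 0.49, 1.14 and 1.09. NCAM1, a neural adhesion molecule, measured 40.2 ± 8.04 and 150 ± 70.3, and CHGB, a granin of secretory granules, measured 10.2 ± 2.92 and 36.4 ± 15.8. No basal marker of 13 tested passed over all genes, and 3 rose adjusted over the list alone. TRIM29 measured 39.7 ± 10.5 and 94.4 ± 12.5, and DST, an integrator of keratin filaments and hemidesmosomes, measured 74.5 ± 14.2 and 184 ± 52.3. The basal median was 0.17, with pair medians of -0.04, 0.7 and 0.22. With 1 library left out it ranged from 0.07 without sgPRKCI replicate 2 to 0.67 without sgPRKCI replicate 1, and the neuroendocrine median from 0.52 without sgControl replicate 1 to 1.36 without sgPRKCI replicate 1. With sgPRKCI replicates 2 and 3 left out the adjusted p-values by camera were 0.792 for the neuroendocrine and 0.859 for the basal list. At a mean of at least 50 the basal median was 0.58, and the neuroendocrine median was 0.29 with its call lost (0.0989). Lost too was the basal call without sgControl replicate 1 (0.0509). With the block 5 neuroendocrine and 5 basal markers rose.

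Cytosolic ribosomal protein mRNAs, the main class of mRNAs with a 5' terminal oligopyrimidine tract, were slightly lower as a list. The adjusted p by camera was 0.0018, and 0.981 with an estimated correlation. None of 71 tested passed on its own, with or without the block, and the median was -0.13. Pair medians were 0.07, -0.37 and -0.11. RPL23A measured 61100 ± 8650 and 48000 ± 1570, and RPS24 measured 68700 ± 8980 and 56000 ± 4370. The call was lost under quantile normalization (adjusted p = 0.874), where the median was -0.02. It was also lost without sgControl replicate 2 (0.163) or sgPRKCI replicate 2 (0.0556), and with 1 library left out the median ranged from -0.06 without sgControl replicate 2 to -0.2 without sgControl replicate 1. The other translation lists did not pass: medians were 0.02 for 41 translation factors, 0.02 for 64 ribosome biogenesis genes and 0.05 for 71 mitochondrial ribosomal proteins, with adjusted p-values by camera of 0.932, 0.966 and 0.767. None of their members passed over all genes, and with the block WDR75 and MRPS27 rose. EIF4B, which stimulates the helicase of the cap-binding complex, measured 13300 ± 942 and 11900 ± 271.

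**Figure D2:**
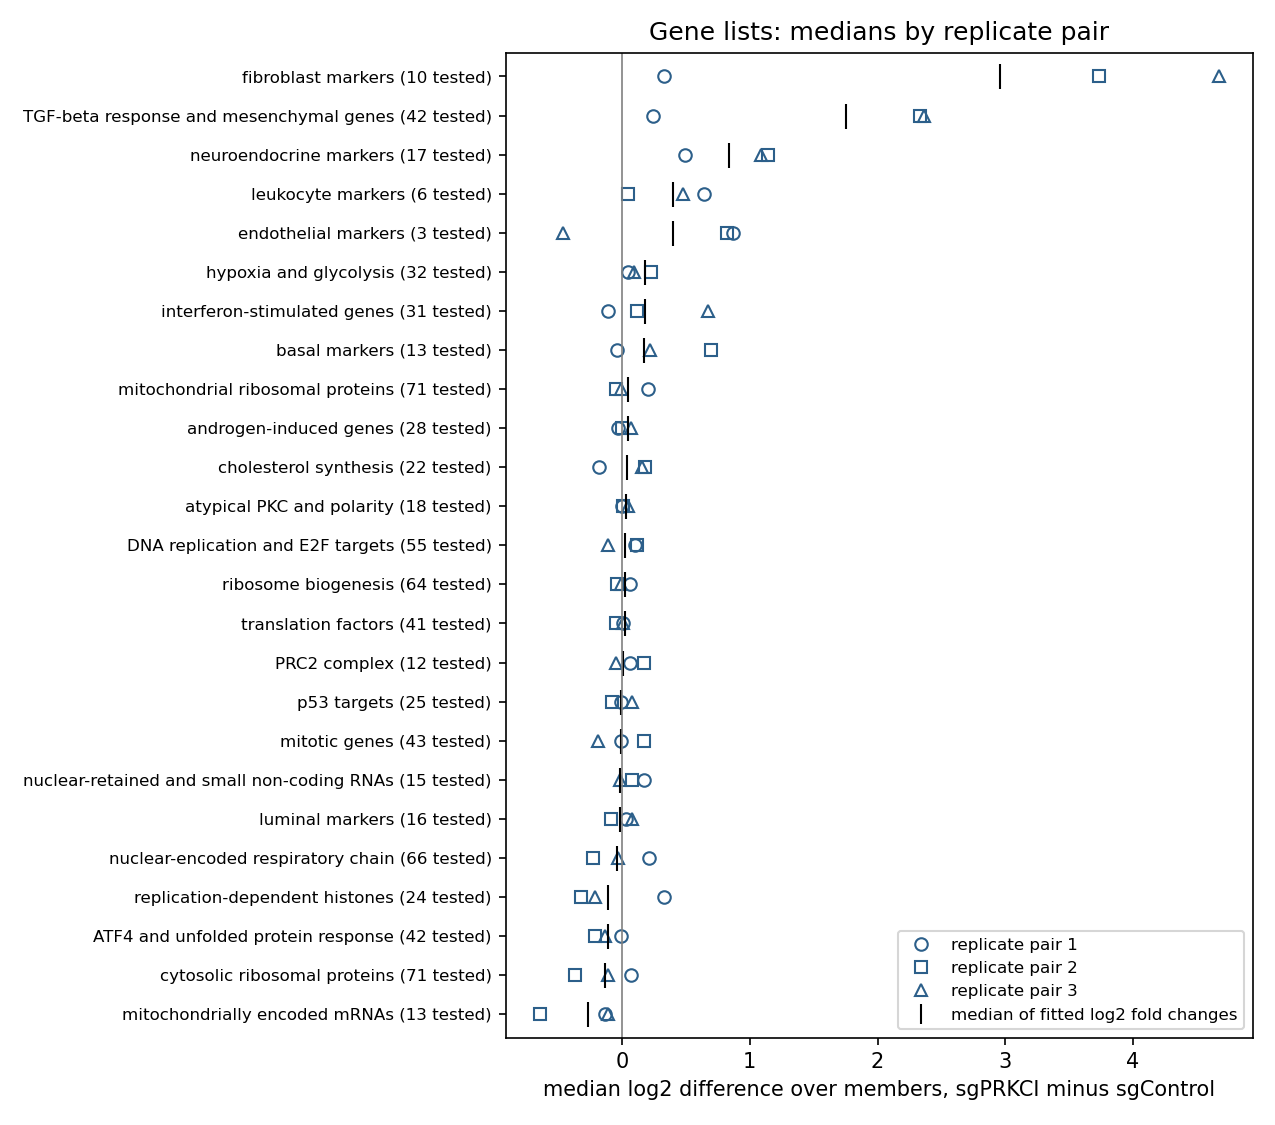
Median log2 difference, sgPRKCI minus sgControl, over the tested members of each of the 25 gene lists. Open symbols are the 3 replicate pairs and the black bar is the median of the fitted log2 fold changes; fibroblast markers reach 3.73 and 4.67 in pairs 2 and 3 against 0.33 in pair 1, and most other lists lie near 0.

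Prostate identity genes did not pass the list test. Of 28 androgen-induced genes and 16 luminal markers tested none passed over all genes, and their medians were 0.05 and -0.02 (adjusted p by camera 0.932 and 0.966). The mean of the luminal list was 0.04 and its test pointed up, against the sign of its median. KLK2, the neighbour and relative of KLK3, measured 1520 ± 348 in sgControl and 977 ± 179 in sgPRKCI, and the potassium channel gene KCNN2 measured 94.9 ± 10.9 and 46.4 ± 12.6. With the block, 4 androgen-induced genes rose and 4 fell, KLK2, KLK3 and KCNN2 among the latter. The luminal gene FOLH1, which encodes prostate-specific membrane antigen, measured 9800 ± 294 and 7930 ± 54.3. Of the luminal genes 3 rose with the block, PSCA among them, and 1 fell, AZGP1 (1240 ± 256 against 795 ± 285). The 12 tested members of the PRC2 complex had a median of 0.01, and none passed with or without the block. The PRC2 list had an adjusted p by camera of 0.966. Of 18 atypical protein kinase C and polarity genes none passed, with a median of 0.03 (adjusted p by camera 0.805). With the block 2 of them rose, including WWTR1, which encodes the Hippo pathway effector TAZ and measured 13.1 ± 2.42 and 96 ± 67.6, with the higher values in sgPRKCI replicates 2 and 3 (124.8 and 144.5 against 18.8 in sgPRKCI replicate 1).

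BST2, an interferon-induced membrane protein that tethers virions, fell from 1950 ± 205 to 416 ± 153 (log2 fold change -2.28, SE 0.25, adjusted p = 0.00447). It was the only gene of 31 tested interferon-stimulated genes to pass, also adjusted over the list alone, and the list had a median of 0.18 (adjusted p by camera 0.486). With 1 library left out that median ranged from -0.05 without sgPRKCI replicate 3 (adjusted p = 0.127) to 0.47 without sgPRKCI replicate 1, where the list passed (0.00405). With the block BST2 and IFI6 fell. Proliferation genes did not pass as lists. The medians were 0.02 for 55 DNA replication genes, -0.01 for 43 mitotic genes and -0.11 for 24 replication-dependent histones, with no member past the threshold, and adjusted p-values by camera were 0.767, 0.966 and 0.856. With the block 1 histone gene rose, H2AC8, and 2 fell, H1-2 and H4C5. The p53 target list (25 tested) had a median of -0.01 and a mean of 0.01, the cholesterol synthesis list (22 tested) 0.04 and the nuclear-encoded respiratory chain list (66 tested) -0.04. None of these 3 lists had a member past the threshold, and their adjusted p-values by camera were 0.966, 0.696 and 0.932. With the block, the p53 target gene TP53INP1 was among 2 that rose and TP53I3 fell, and the respiratory chain gene NDUFV2 rose and CYC1 fell. In the ATF4 and unfolded protein response list (42 tested, median -0.11), CEBPB measured 1320 ± 286 and 718 ± 212 and DDIT3, a stress-induced transcription factor, measured 1200 ± 309 and 755 ± 254. That list had an adjusted p by camera of 0.113, and 0.0488 with the block, where 3 members fell, CEBPB and DDIT3 among them, and 1 rose. With the block and an estimated correlation the adjusted p was 0.993, and with 1 library left out the median ranged from 0.01 without sgControl replicate 1 to -0.29 without sgPRKCI replicate 1. In the hypoxia and glycolysis list (32 tested, median 0.18), the glucose transporter gene SLC2A1 measured 337 ± 64 and 552 ± 90.8. Its adjusted p by camera was 0.0744, and 0.0182 with the block, where 4 members rose and 1 fell. With the block and an estimated correlation the adjusted p was 0.752. SLC2A1 and 2 more of the 4 were highest in sgPRKCI replicates 2 and 3, where the fibroblast genes stood high: in sgPRKCI replicates 1, 2 and 3, SLC2A1 measured 447.7, 613.7 and 594.4, the glucose transporter gene SLC2A3 27.1, 202.2 and 181.7, and the collagen hydroxylase gene P4HA2 193.2, 594.3 and 663.6. The list also passed under total-sum (0.0434), upper-quartile (0.0413) and quantile (0.0216) scaling, and its median ranged from 0.01 without sgControl replicate 2 to 0.3 without sgControl replicate 1.

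Signs of RNA fraction and of other cells were compared in the same way. The 13 mitochondrially encoded mRNAs, which are translated inside mitochondria, had a median of -0.27 (adjusted p by camera 0.103, 0.0473 under total-sum scaling and 0.00137 with the block). With the block and an estimated correlation the adjusted p was 0.993. With 1 library left out the median ranged from -0.72 without sgControl replicate 3 (adjusted p = 9.78e-06) to 0.04 without sgPRKCI replicate 3 (0.953). They took 2.78%, 2.79% and 1.21% of reads in sgControl replicates 1, 2 and 3, and 2.38%, 2.06% and 1.13% in sgPRKCI. The 15 nuclear-retained and small non-coding RNAs had a median of -0.02 and a mean of 0.13, the direction of the test (adjusted p by camera 0.932). Within them, the nuclear RNA MALAT1 measured 10147.0 and 9600.9 in the libraries numbered 1 and between 25769.2 and 31445.0 in the other 4. MALAT1 falls outside the naming rule and was chosen after its values were seen. Of 6 leukocyte markers none passed (median 0.4, adjusted p by camera 0.0744, and 0.0488 with the block). With the block and an estimated correlation the adjusted p of the leukocyte list was 0.752. Of 8 endothelial markers 3 could be tested, too few for the list test, with a median of 0.4. TEK, an angiopoietin receptor gene, rose adjusted over that list alone (2.54 ± 0.658 against 29.9 ± 21.9) and with the block, and was highest where the fibroblast genes stood high, at 4.7, 41.8 and 43.3 in sgPRKCI replicates 1, 2 and 3. The endothelial genes VWF (91.9, 65.1 and 41.5) and PECAM1 (22.4, 9.3 and 11.2) were highest in sgPRKCI replicate 1 of these 3 libraries. CD68 of the leukocyte list rose with the block (192 ± 69.8 against 290 ± 84.7). Apart from the TGF-beta, fibroblast, neuroendocrine, basal, interferon and endothelial lists, no list had a member past the threshold adjusted over the list alone.

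**Figure D3:**
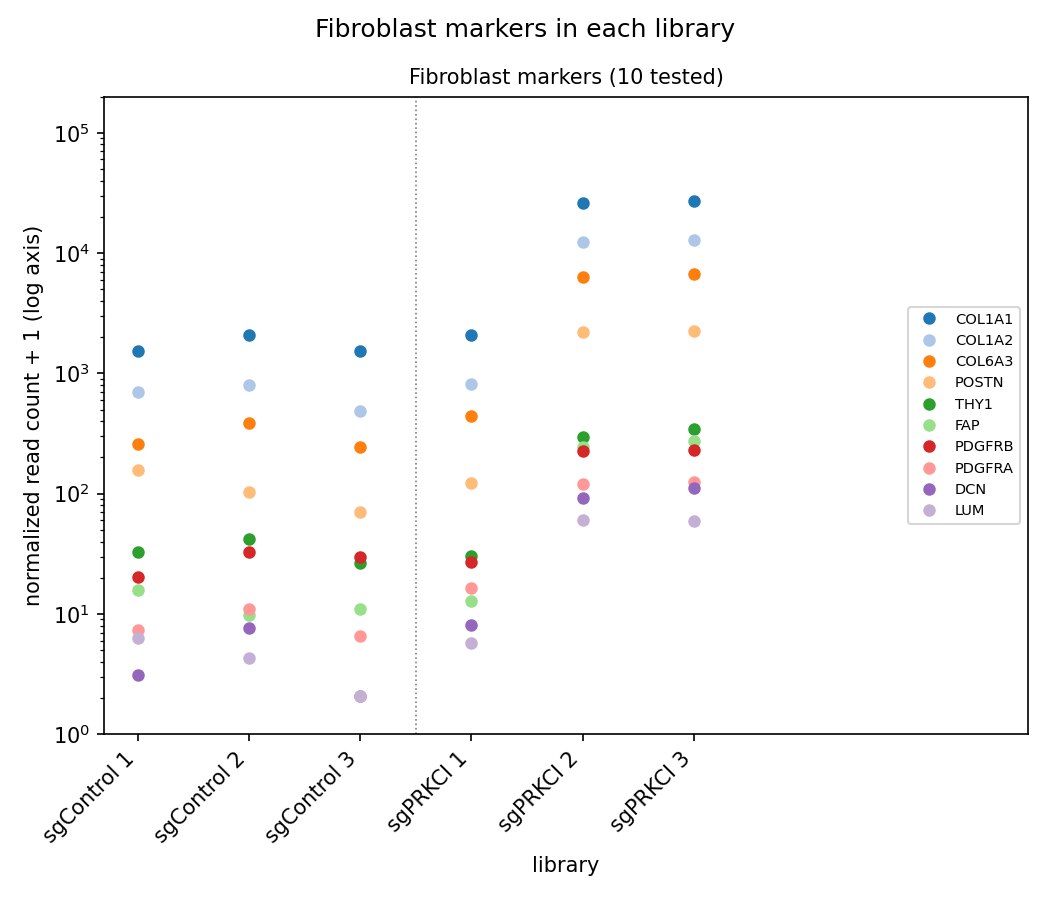
Normalized read counts + 1, on a log axis, of the 10 tested fibroblast markers in each of the 6 libraries, with 1 point per gene and library. COL1A2 lies at 12276.1 and 12825.5 in sgPRKCI replicates 2 and 3 and between 487.8 and 815.2 in the other 4 libraries.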

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

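The fits with a block in edgeR or DESeq2 and those that leave out 2 libraries were chosen after the data were seen. All 162 genes kept their direction under every alternative that tested them, but the count moved. Every sgPRKCI library of these genes lay on one side of every sgControl library, so a change of direction was hardly possible. With the replicate block 1545 genes differed (913 higher, 632 lower), and 9 lists; with edgeR and the block 1810 (1014 and 796); with DESeq2 and the block 1115 (635 and 480). DESeq2 without the block gave 821 (558 and 263) and edgeR 172 (66 and 106). In the simulation without pair effects 27 of 185 DESeq2 calls were false, against 3 of 126 for edgeR. With pair effects 1 of 151 DESeq2 calls and 0 of 85 edgeR calls were false. Library weights gave 1877 (1213 and 664) and 9 lists, and the filter at a mean of 50, which tests fewer genes, gave 86 (36 and 50). Leaving out 1 library gave 74 to 937 genes, 30 to 724 higher and 41 to 213 lower, and 5 to 10 lists. Without both replicate-1 libraries 1486 differed (1026 and 460) and 11 lists. With sgPRKCI replicates 2 and 3 left out, where the lone sgPRKCI library is assumed to vary like the others, 127 differed (26 and 101), 103 of them shared with the 162, and 8 lists. The share of higher genes stayed between 36.4% and 38.5% under the other scalings, against 41.4%, and no scaling moved the median of all genes beyond 0.04.

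PRKCI ranged from -0.31 to 0.23 and passed in no fit; its sign turned without sgControl replicate 1, without sgPRKCI replicate 3, and with sgPRKCI replicates 2 and 3 left out. For the 24 largest changes, 498 of 528 alternative values stayed past the threshold. None changed direction, which their selection for groups without overlap made nearly certain. Among lists, 0 passed with an estimated correlation and 0 with fry. Mitochondrial ribosomal proteins passed at -0.16 without sgPRKCI replicate 1, at 0.18 without sgControl replicate 1, and at 0.5 with sgPRKCI replicates 2 and 3 left out (adjusted p = 0.0127, 0.012 and 3.85e-09). In the last of these fits the respiratory chain turned to 0.37, histones to 0.69 and interferon-stimulated genes to -0.22. The cause of these moves was not tested. The block added 1383 genes, those named in the report included, and ended none, and it changed no list's call beyond those named there. Lists that did not pass otherwise could pass with 1 library left out, such as cholesterol synthesis without sgControl replicate 1 (adjusted p = 1.85e-05) and DNA replication without sgPRKCI replicate 3 (0.000265). Depth limits genes near a mean of 10, where 1 read is worth 0.7749 to 1.178 normalized counts.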

Other observations

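The tests of patterns here were chosen after the results were seen, except the counts over other splits of the libraries. Cancer/testis genes were counted by family, with the families chosen after the falls were seen and not tested as a set. Of 24 tested genes of 13 germline families such as MAGEA, GAGE, PAGE, XAGE and VCX, 13 fell, none rose, and 18 had every sgPRKCI library below every sgControl library, with a median log2 fold change of -1.96. Without the 5 that are among the 12 largest falls, 8 of 19 fell, with a median of -1.53. This is no independent check, since the families were chosen after the falls were seen. With the block 19 of the 24 fell. Among genes chosen after their values were seen, MAGEA1 went from 351 to 39.1, VCX from 2430 to 569, and the X-linked antigen gene CT83 from 66.4 to 0.258 normalized reads. X-linked genes made up 20% of the 95 lower genes and 3.3% of the genes tested (Fisher's exact test across genes, which are not independent, odds ratio 7.57, adjusted p = 5.19e-09 over 23 chromosomes). Of the 19 X-linked lower genes 8 lay outside the 13 families, so the X-linked share is largely the same fall counted again. Chromosome 21 had a higher share of its genes lower, 8 of 163 (4.91%) against 19 of 509 (3.73%) for X, at an odds ratio of 8.99 (adjusted p = 8.42e-05).

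Other genes past the threshold are named here after their values were seen. WNT5A, a non-canonical Wnt ligand, rose from 89.2 to 346, the cyclin gene CCND2 from 79.7 to 382, and the nuclear receptor gene NR2F1 from 6.19 to 59.7. DPYSL2 rose from 96 to 386, DPYSL3 from 165 to 596 and DPYSL5 from 52.1 to 261. The growth factor gene MDK fell from 6710 to 3350.

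The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 162 genes and the highest of the others gave 0, so 1 split of 10 reached the real count. Among the 4 splits that part all 3 pairs, the blocked fit gave 1545 genes for the real split and at most 0 for the others, so 1 of 4 reached it. Every other split mixed both guides in each group, so the difference between the guides added to the spread within groups. Counts of 0 were therefore likely in advance and do not measure how many genes are called without a difference. For gene lists the real split passed 5 and another split 12, and all 10 splits passed at least as many as the real one. The number of lists that pass at the preset correlation therefore does not set the real split apart from the others.

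The fibroblast genes stood high in sgPRKCI replicates 2 and 3 and not in sgPRKCI replicate 1. A mislabelled sgPRKCI replicate 1 is argued against by the Y-linked genes, whose median in pair 1 was 5.08 on the log2 scale, against 4.91 and 5.12 in pairs 2 and 3. RNA of a fibroblast-like source present in the same share in both libraries is a candidate explanation: the log2 ratio of replicate 3 to replicate 2 had an SD of 0.1 over the 10 genes, at percentile 0.16 of 10000 random gene sets matched on level, and COL1A1, the most abundant of the list and chosen after its values were seen, read 25837.6 and 26867.4. The 10 genes were each over 4-fold above the other 4 libraries, which held them at a median of 3.88% to 7.43% of that level. The random sets were matched on level only, and genes regulated together would also keep a narrow ratio, so the small SD cannot favour that source. A response to the guide in these 2 libraries, or a mesenchymal subset of LNCaP cells, stays open, since the smallest pair median, 0.33, rests on 1 library.

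The 16 tested Y-linked genes were higher in sgPRKCI, 13 of them past the threshold, with a median log2 fold change of 5.16. In 15 of the 16, every sgPRKCI library lay above every sgControl library, and sgControl held a median of 1.47% of the sgPRKCI level. No other chromosome had a median beyond 0.09 in size. The groups may therefore come from cell populations that differ in the presence of the Y chromosome, a difference that need not come from the guide. A response to the guide cannot be told apart from this with 1 control and 1 targeting population. Either would raise Y-linked genes in every pair, and the smallest pair median was 4.91.

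The fall of germline genes was weighed in the same way. Fewer copies of the X chromosome are argued against by the median of 509 tested X-linked genes, -0.02. Summed over all 35 measured genes of the 13 families, normalized values went from 17100 ± 2740 in sgControl to 8190 ± 2990 in sgPRKCI. That is a log2 ratio of -1.06, with pair values of -0.8, -1.41 and -1.11. The families' total therefore fell, which reads moved only among these genes would not give. The sum cannot decide this for low members such as GAGE1 (218 in sgControl) and PAGE2B (137), whose reads could move unseen in it. A response to the guide and a difference between cell populations that predates it both remain open. They cannot be told apart, since guide and population go together in these groups. Either would lower these genes in every pair, and the pair median closest to 0 was -1.8. A candidate explanation that would cover the Y-linked and germline genes together is divergence of the populations before treatment, which no test here decides.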
